A study of Homo sapiens with 16 samples.

How the data were processed

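RNA immunoprecipitation with an anti-Myc antibody was done on H1299 cells that stably expressed Myc-tagged PABPC1, and ribosomal RNA was removed from immunoprecipitated and input RNA before libraries were made, per the labels' protocols. The submitters' processing notes name cutadapt 1.9.3, a read trimmer, HISAT2 2.0.4, an aligner, and the genome build hg19, without their order or settings. The peak names in the deposited lists begin with MACS, so a version of that caller made them. The version, the control library, the threshold and the way strand was assigned are not given in the sources used here. Each list belongs to 1 sample, and no pooling of samples is stated.

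The authors deposited for each of 8 samples a list of peaks with start, end, strand and a score per peak. The score ranged from 13.02 to 3233.06, and between 8.17% and 11.0% of a list's peaks had a score of 3100 or more, so the strongest peaks are tied or nearly so. Its unit is not stated, and its lowest value is close to −10 times the log10 of a p of 0.05. It was used only to rank peaks within a list. The number in the names of the peaks ran up to 39095 to 48239, and the lists held 49.7% to 52.1% as many peaks as that number, so the numbering has gaps. The names of the lists carry the label mRNA, but what the missing numbers stood for is not given in the sources used here. No list held peaks on the mitochondrial genome or on unplaced sequences. No chromosome had a peak past its end in hg19, while 14 of 24 did in hg38, and all coordinates are hg19, counted from 1.

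Samples were grouped by the titles in the sample record. The names of 6 of the 8 lists give another condition than the record of the sample that holds them. Under either reading the 4 pairs and the 2 factors are the same sets of lists, so the counts do not depend on the reading and their meaning does. No list was used here for the 8 samples titled K512R.

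The planned unit was the gene. The gene table used here is for another genome build (GRCh38.p14) than the lists, so peaks were not assigned to genes, and regions took the place of genes, which had been planned as an alternative. For the same reason the planned tests of 16 fixed gene lists, of U content and of place in UTRs or coding sequence were not run, nor were their alternatives. The test of counts was not run because the lists hold no counts. Peaks of all 8 lists on the same strand that overlapped by at least 1 bp were joined into regions. A region was lost where it had a peak in 2 of 2 lists of the starting pair and 0 of 2 of the other, and gained in the reverse case. The regions named are examples from the 12 lost and 12 gained ones per comparison whose poorer score percentile over the 2 lists was best. Most of these are tied at a score of 3100, and ties were broken by position, so the named regions are a subset of equally scored ones.

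An exact test of 2 lists against 2 has 3 splits and cannot pass 0.05, so counts between pairs were given without a p-value and set beside the other 2 splits of the same 4 lists. Over the 2 factors, values per list were compared by exact 2-sided permutation of 4 lists against 4 (70 orders), and counts of regions by all 35 splits. The similarity of replicates was tested over all ways to pair the lists. Overlaps of changes were compared with n1 × n2 / N over the regions that could change in both. Odds ratios carry 95% intervals that cover counting error only, and Mantel-Haenszel odds ratios were taken within 3 tertiles of the score. The rule for lost and gained regions was tested on simulated presence over the 36802 regions, in which each region had its own mean frequency and 100 were set to be lost and 100 gained. Those regions were set to the pattern the rule looks for, so finding them checks how the rule was coded and not its power. The frequency was the mean over the 4 lists compared, so real differences between the pairs entered it. The simulation therefore gives no background free of an effect. Among regions not set to change, it gave 802 lost and 845 gained for B against A and 613 and 649 for C against A. For D against C it gave 965 and 908, and for D against B 576 and 597.

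Comparisons, groups, the main tests and the alternatives of score, list length, overlap, replicates and presence rule were fixed before the data were examined. The following were chosen after the lists had been explored: covered length, mean width, the bounds of 1000 and 2000 bp, the odds ratios of wide regions, coverage along regions, the shift of peak ends with its tolerance of 20 bp, shares per chromosome, and neighbouring regions. That exploration also looked at other width bounds and at coverage in 3 width classes. The depth of each sample is unknown, so precision rests on the number of lists, and a longer list can come from deeper sequencing. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.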

Results

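RNA bound to PABPC1, the main cytoplasmic poly(A)-binding protein, was measured by RNA immunoprecipitation followed by sequencing (RIP-seq) in H1299 cells, an established human lung carcinoma line. The cells stably expressed Myc-tagged PABPC1, either wild type (WT) or with the K512R change, a lysine replaced by arginine. They were left untreated or given 500 µM sodium arsenite (AS), an oxidative stressor that induces stress granules, which are cytoplasmic bodies that hold stalled mRNAs. By its title, the study concerns SUMO modification of PABPC1 and the mRNAs held in stress granules. Of the 16 samples of the series, 8 had a list of peaks, stretches of the genome where the authors' caller found enriched reads, and these 8 lists are described here. No list was used here for the other 8 samples, all titled K512R, so by the record no list of K512R cells is among the 8, while by the names of the lists 4 are. Read depth is unknown, since the lists give no counts.

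The 8 lists form 4 pairs of replicates, and for 3 of the pairs the sample record and the name of the list give different conditions. In pair A both give untreated WT, and the record adds that it is the immunoprecipitate (IP). Pair B is recorded as the input RNA of untreated WT cells and named for WT with AS. Pair C is recorded as the IP of WT cells with AS and named for untreated K512R. Pair D is recorded as the input of WT cells with AS and named for K512R with AS. Grouping followed the record, 6 of the 8 lists carry the conflict, and which reading is right was not settled. By the names, WT and K512R with and without AS each have a pair of lists. The names thus cover the conditions of the series, while the record covers only WT. The pairs are therefore called A to D, and each comparison is given with both readings. Nothing in the labels says whether replicates came from separate cultures, so the spread between them may be technical.

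The lists held between 19953 and 25111 peaks each, 175749 in all. Peaks that overlapped on the same strand were joined into 36802 regions with a median width of 180 bp. Of these, 10872 regions (29.5%) had a peak in all 8 lists and 6330 (17.2%) in 1 list alone. Replicates resembled each other most, with a mean Jaccard index, the share of regions in common, of 0.737 over the 4 pairs. No other way of pairing the 8 lists gave as high a mean, the highest of them being 0.716 (p = 0.00952, exact 1-sided test over all pairings, the smallest p it can give). Lists of A and C, and lists of B and D, overlapped with a mean index of 0.685. Lists across these sets overlapped less, with a mean of 0.540 and a range of 0.522 to 0.559. The 8 lists thus fell into a set of A and C and a set of B and D. Where 2 lists of different pairs each had 1 peak in a region, both ends of the peak were identical in 82.1% to 84.8% of the regions in the comparisons made here.

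**Figure D1:**
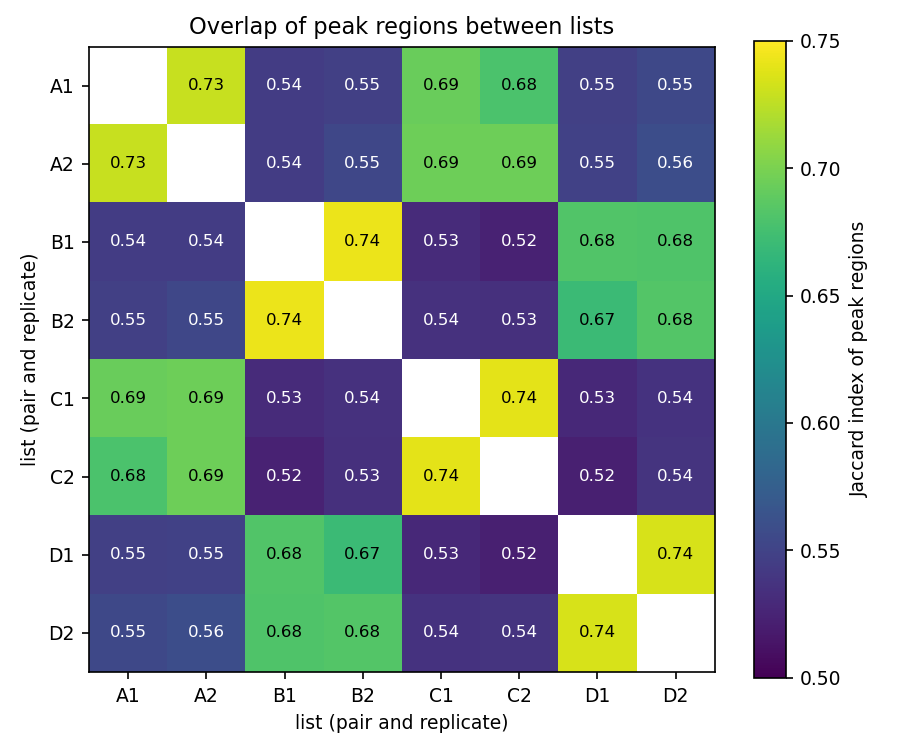
Jaccard index of peak regions (colour and printed value) for each 2 of the 8 lists, with pairs A to D and replicate numbers on both axes. Replicates sit at 0.729 to 0.743, lists of A with C and of B with D at 0.670 to 0.695, and all other combinations at 0.522 to 0.559.

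Pair B was compared with pair A, which by the record sets WT input against WT IP and by the list names sets AS against no treatment in WT cells. Between them, 3544 regions were lost, meaning that they had a peak in both lists of A and in neither of B, and 3021 were gained. The lost regions were 19.1% of the 18525 regions found in both lists of A, and 12803 regions were in all 4 lists. When every list was limited to its 19953 best-scoring peaks, the length of the shortest list, 2995 regions were lost and 3276 gained. The excess thus turned from lost to gained regions, and the share of lost among changed ones moved from 54.0% to 47.8%. Equal list lengths draw lost and gained counts together by construction, so this turn does not test the direction of change. Among the best-scoring lost regions were 3 of over 2000 bp, on chromosome 16 at 81076766 to 81080951 (plus strand, 4186 bp), chromosome 17 at 80559179 to 80562483 (plus strand, 3305 bp) and chromosome 1 at 25226002 to 25229157 (minus strand, 3156 bp). A pair of lost regions lay close together on the plus strand of chromosome 12, at 57908737 to 57910430 and at 57919131 to 57920171. Best-scoring gained regions included chromosome X at 153715645 to 153717421 (minus strand, 1777 bp), chromosome 11 at 16776418 to 16777880 (plus strand, 1463 bp) and chromosome 1 at 226259052 to 226259703 (plus strand, 652 bp). An exact test of 2 lists against 2 has only 3 splits and cannot pass 0.05, so the counts are given without a p-value beside the other 2 splits of the same lists, which gave 235 to 345 regions in either direction. Lost regions had poorer scores than those not lost, with a median percentile within their lists of 29.8 against 62.3, but 581 (16.4%) scored above the median in both lists of A.

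Pair C was compared with pair A, which by the record sets AS against no treatment in WT IP and by the names sets K512R against WT without treatment. Here 1829 regions were gained and 598 lost, and 16479 were in all 4 lists. The gained regions exceeded the 419 to 640 regions in either direction of the other splits, and the lost ones did not. With every list at its 19953 best-scoring peaks, 988 regions were gained and 939 lost. The share of lost among changed regions then moved from 24.6% to 48.7%. Lists of equal length draw lost and gained counts together by construction, so this shift does not test the excess of gains. At that length both directions exceeded the other splits, which gave 389 to 455. Best-scoring gained regions included chromosome 16 at 30207122 to 30208422 (plus strand, 1301 bp), chromosome 15 at 44093716 to 44094449 (plus strand, 734 bp) and chromosome 11 at 134113013 to 134113188 (plus strand, 176 bp). Best-scoring lost regions included chromosome 11 at 8707225 to 8711392 (plus strand, 4168 bp), chromosome 10 at 79395961 to 79396764 (minus strand, 804 bp) and chromosome 12 at 42719726 to 42719932 (minus strand, 207 bp). Near the second of these, a region on the same strand of chromosome 10 at 79397023 to 79398098 was gained. On the plus strand of chromosome 12, a lost region at 133287393 to 133287653 lay next to a gained one at 133287668 to 133288215. A lost region can thus have a gained peak close by. How often this held over all changed regions was not counted. Only 5.69% of gained and 14.5% of lost regions scored above the median in both lists that held them.

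Pair D was compared with pair C, which by the record sets input against IP of WT cells with AS and by the names sets AS against no treatment in K512R cells. This comparison had the most changed regions of the 4, with 5295 lost and 2303 gained. The lost regions were 25.3% of the 20905 found in both lists of C. The other splits of these lists gave 263 to 428 regions in either direction. With every list at its 19953 best-scoring peaks, 3502 regions were lost and 3247 gained. The share of lost among changed regions moved from 69.7% to 51.9%, a shift that equal list lengths favour by construction. Best-scoring lost regions included chromosome 10 at 72181472 to 72188374 (plus strand, 6903 bp), chromosome 1 at 36805225 to 36807773 (minus strand, 2549 bp) and at 206905383 to 206907630 (plus strand, 2248 bp), and chromosome 11 at 62437113 to 62439237 (minus strand, 2125 bp). The region on chromosome 11 at 134113013, gained in C against A, was lost here. Best-scoring gained regions included the regions on chromosome 11 at 8707225 and on chromosome 10 at 79395961 that were lost in C against A. Regions on chromosome 1 at 8926338 to 8926560 (minus strand), 38484925 to 38485055 (plus strand), 45981326 to 45981479 (minus strand) and 226259052 to 226259703 (plus strand) were among the 12 best gained ones both here and in B against A.

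Pair D was compared with pair B, which by the record sets AS against no treatment in WT input and by the names sets K512R against WT, both with AS. In all, 1386 regions were lost and 1090 gained, against 307 to 587 in either direction in the other splits, and 14393 regions were in all 4 lists. Both counts lay under those of B against A and D against C. Best-scoring lost regions included chromosome 16 at 2811562 to 2818262 (plus strand, 6701 bp), chromosome 19 at 2428163 to 2430950 (minus strand, 2788 bp) and chromosome 10 at 102747293 to 102749210 (plus strand, 1918 bp). On the same strand of chromosome 19 a region at 2426114 to 2427044 was gained, as were chromosome 11 at 62439425 to 62440960 (plus strand, 1536 bp) and chromosome 12 at 25357025 to 25357997 (plus strand, 973 bp). Other named lost regions also had a gained one close by on the same strand. These were chromosome 11 at 75115716 (gained at 75114333), chromosome 16 at 47007406 (gained at 47006454) and chromosome 1 at 226250408 (gained at 226249552). The region on chromosome 12 at 42719726, lost in C against A and in B against A, was gained here. Of the changed regions, 10.9% of lost and 12.1% of gained ones scored above the median in both lists that held them.

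**Figure D2:**
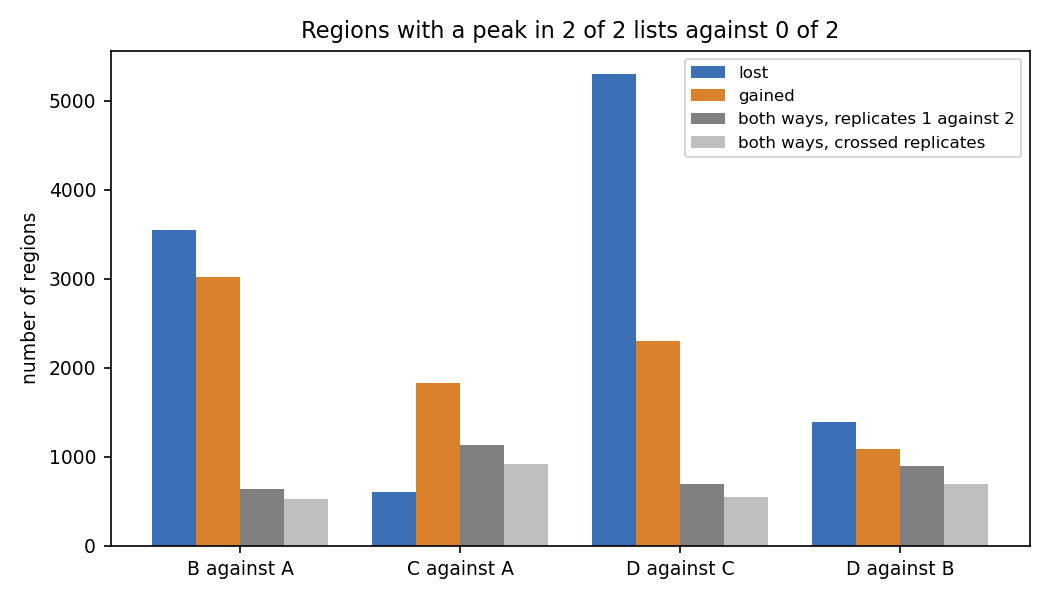
Number of regions lost and gained (vertical axis) in the 4 comparisons of list pairs (horizontal axis), with the lost and gained regions of the other 2 splits of the same 4 lists added together in grey. B against A and D against C stand at 6565 and 7598 changed regions against at most 691 in the other splits, and C against A and D against B at 2427 and 2476 against at most 1134.

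Over all 8 lists, 1875 regions had a peak in every list of A and C and in none of B and D, and 1106 had the reverse. By the record this sets IP against input, and by the names no treatment against AS. The total of 2981 was reached by 1 of the 35 splits of the 8 lists into 4 and 4, the real one, and the highest of the others gave 90. Of these splits, 32 part replicates and 3 keep them together, with totals of 42, 90 and 2981, so with pairs as the units no share under 0.05 can be reached. The second factor sets A and B against C and D, which by the record is no treatment against AS and by the names WT against K512R. It gave 18 regions only in A and B and 24 only in C and D, and 19 of the 35 splits gave a total as large as this 42. The comparisons B against A and D against C use no list in common. Of the regions that could be lost in both, 1875 were lost in both, where independent sets of these sizes would share 455, and 1106 were gained in both where 172 would be shared. C against A and D against B also use no list in common. In them, 18 regions were lost in both (6.47 for independent sets) and 24 gained in both (11.2). By definition, the 1875, 1106, 18 and 24 regions are those already counted above, so their sharing is no separate support. By the same presence pattern, 66 regions in both lists of B and C and in none of A and D were gained in C against A and lost in D against B, and equally gained in B against A and lost in D against C (15.9 for independent sets in either case). The reverse pattern held for 24 regions (6.15). Regions are not independent replicates, and poorly scored regions change more often in every comparison, so these overlaps describe the lists.

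The lists of B and D were shorter and the peaks they held narrower than those of A and C. Widths here compare all peaks of a list and do not show that shared peaks narrowed. In regions with 1 peak in both lists, both ends were identical in 84.0% to 84.8% for B against A and 82.1% to 82.8% for D against C. The number of peaks was 20734.5 ± 602 in B, 20462 ± 720 in D, 22031 ± 73.5 in A and 24647 ± 656 in C (SD, n = 2 each). Over the 4 lists of B and D it fell by 11.7% relative to A and C, and the covered length went from 9.03 ± 0.788 to 6.94 ± 0.185 Mb (SD, n = 4 each). Median peak width was 192 ± 2.94 bp in A and C and 184.75 ± 1.71 bp in B and D (SD, n = 4 each). Mean peak width was 387 ± 7.97 and 337 ± 4.01 bp, and the share of peaks over 1000 bp 8.44% ± 0.422 and 6.36% ± 0.304 (SD, n = 4 each). In each of these measures every list of B and D lay below every list of A and C, with p = 0.0286 in an exact 2-sided permutation test, the smallest that 4 lists against 4 can give. After Benjamini-Hochberg adjustment over the 14 tests of 7 measures and 2 factors the value was 0.0667, so none passed 0.05. These tests take the 8 lists as independent, and with the pairs as units no exact test could pass 0.05. Between A and B on one side and C and D on the other, the exact permutation p of these measures ranged from 0.429 for peaks to 0.829 for the share over 1000 bp (unadjusted, n = 4 each).

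**Figure D3:**
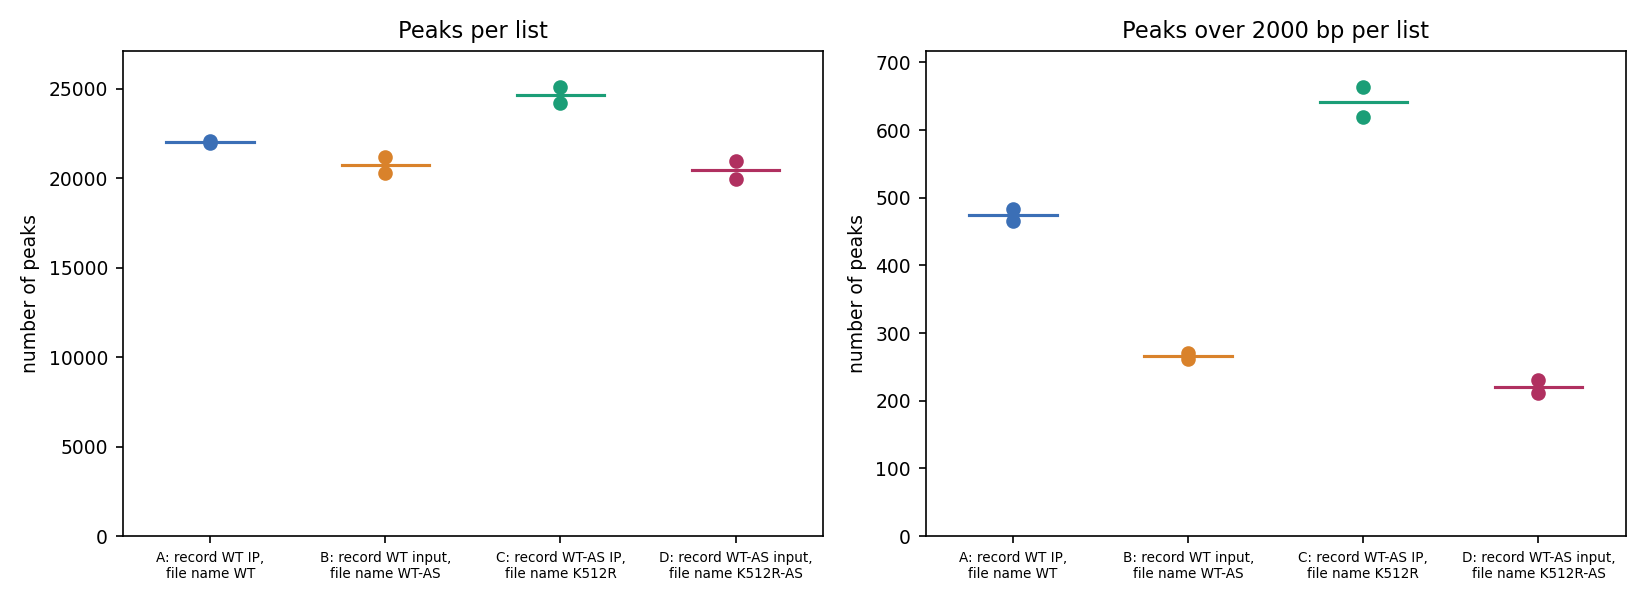
Number of peaks (left) and of peaks over 2000 bp (right) in each list, as points, with the mean of the 2 lists of a pair as a line and both readings of each pair on the horizontal axis. Peaks over 2000 bp number 466 and 484 in A and 619 and 664 in C, against 261 and 270 in B and 211 and 230 in D.

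Wide regions were lost more often than narrow ones in B against A and in D against C. Here the width of a region is the summed width of its peaks in a list. It was averaged over the 2 lists of the pair that held the region. In B against A, 28.1% of 1568 regions over 1000 bp were lost, and 18.3% of 16957 narrower ones (odds ratio 1.74, 95% interval 1.55 to 1.96). In D against C, 36.9% of 1929 and 24.2% of 18976 were lost (odds ratio 1.83, 1.66 to 2.02). Over 2000 bp the lost share was 42.1% in B against A and 54.1% in D against C. Fisher's exact test over regions gave adjusted p = 1.1e-18 and 3.9e-31 in these comparisons (Benjamini-Hochberg over 8 tests), which describes the lists, since regions are not independent replicates. In C against A the wide regions were lost less often, 1.40% against 3.40% (odds ratio 0.40, 0.264 to 0.621). In D against B the lost shares were 8.73% and 7.79% (odds ratio 1.13, 0.918 to 1.40), and over 2000 bp 13.4% against 7.79% (odds ratio 1.83, 1.23 to 2.71). Within tertiles of the score, the odds ratio of loss over 1000 bp was 2.94 in B against A, 2.89 in D against C, 1.65 (1.32 to 2.07) in D against B and 0.564 (0.365 to 0.870) in C against A. Among gained regions the interval of the unstratified odds ratio at 1000 bp included 1 in all 4 comparisons. Within tertiles it lay above 1 in C against A (1.897, 1.58 to 2.27) and D against B (1.62, 1.26 to 2.08), as did the unstratified ratio over 2000 bp (1.59 and 2.08).

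**Figure D4:**
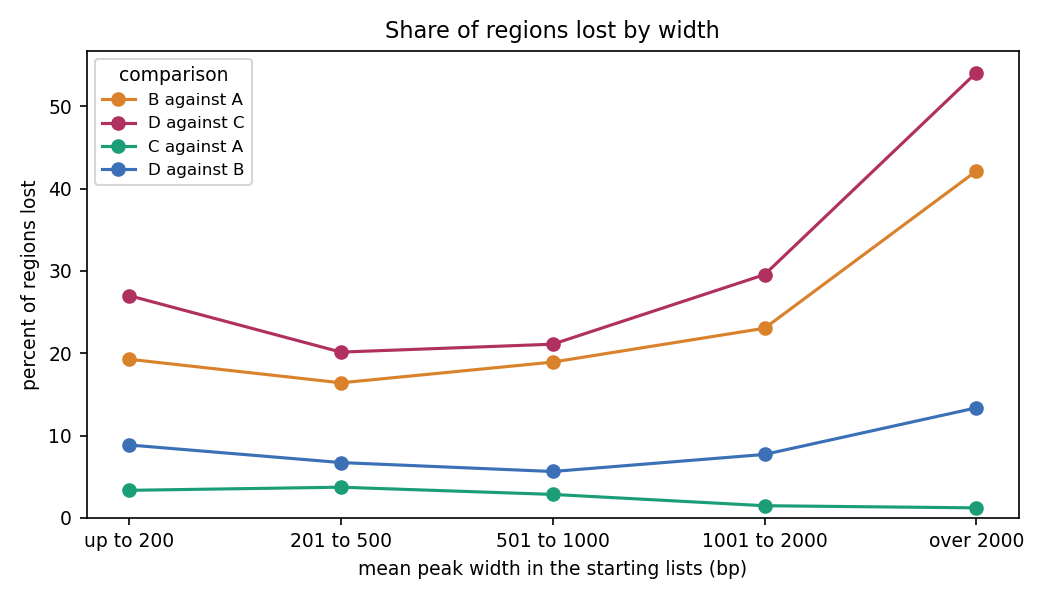
Percent of regions in both starting lists that were lost (vertical axis) by mean peak width in those lists (horizontal axis, 5 classes in bp, peaks of a list in the same region summed) in the 4 comparisons. D against C goes from 27.0% in the narrowest class through 20.1% in the next to 54.1% over 2000 bp, B against A from 19.3% through 16.4% to 42.1%, and D against B from 8.85% through a lowest value of 5.63% to 13.4%, while C against A stays between 1.21% and 3.72%.

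Within the 933 regions over 2000 bp, peaks covered less of the 3' end than of the 5' end in every list. The last 10% of these regions, counted from the 5' end on their strand, was covered at 79.8% and 82.2% of the level of the first 10% in the lists of A, 83.4% and 80.8% in B, and 87.1% and 88.0% in C. In D it was 66.2% and 64.9%. The difference of A and C from B and D in this ratio had p = 0.143, and that of A and B from C and D p = 0.429 (exact 2-sided permutation tests, n = 4 each). In regions with 1 peak in both lists compared, the 3' end of the peak was shorter by more than 20 bp in 4.54% to 4.996% of regions in D against B and longer in 1.63% to 1.97%. In D against C it was shorter in 4.69% to 4.99% and longer in 2.03% to 2.58%, in C against A shorter in 2.52% to 3.41% and longer in 3.19% to 3.90%, and in B against A shorter in 2.64% to 3.05% and longer in 2.98% to 3.71%. The 5' end was more often shorter than longer in D against B (2.31% to 2.55% against 1.51% to 1.81%), D against C (2.74% to 3.32% against 1.55% to 1.83%) and B against A (2.21% to 2.52% against 1.67% to 2.19%). In C against A it was shorter in 1.75% to 2.20% and longer in 1.94% to 2.68%. The place of these regions in transcripts was not analysed here.

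**Figure D5:**
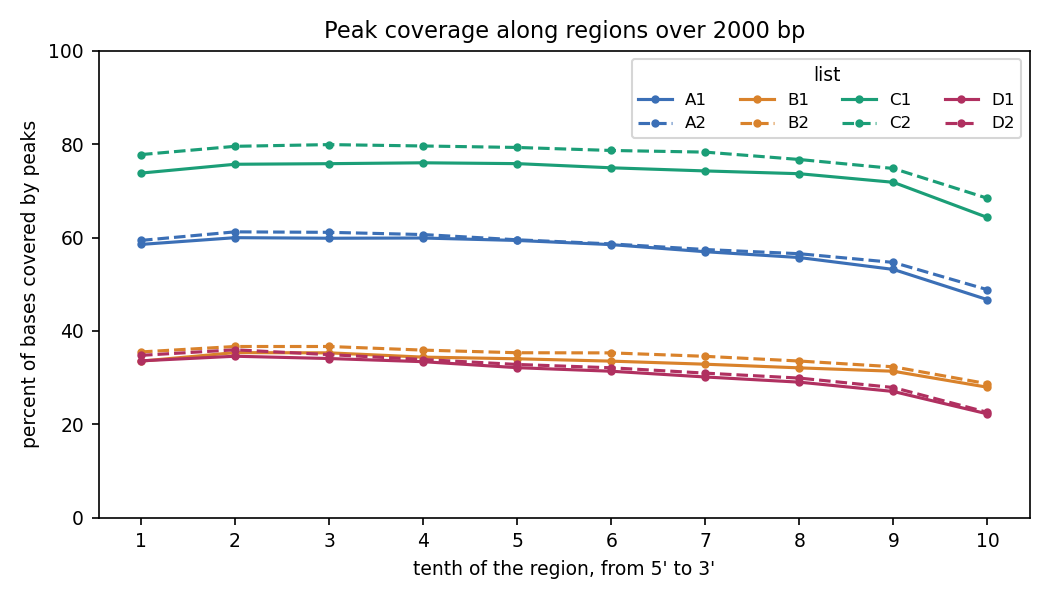
Percent of bases covered by peaks (vertical axis) along the 933 regions over 2000 bp, in 10 equal bins from the 5' to the 3' end (horizontal axis), with 1 line per list. Coverage falls towards the 3' end in all 8 lists, and relative to the 5' end it ends lowest in D, from 33.6% to 22.3% and from 34.8% to 22.6%.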

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

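For 4 measures the difference of C from A and that of D from B went in opposite directions in every list, and all of them except median width were chosen after the lists had been explored. By the record these are the AS effects in IP and in input, and by the names the K512R effects without and with AS. Median peak width was 5 bp lower in C than in A and 2.5 bp higher in D than in B, a difference of 7.5 bp between the effects. Mean peak width was 13.6 bp higher in C than in A and lower in D than in B (334 against 340 bp), a difference of −19.4 bp. The share of peaks over 1000 bp was 0.717 percentage points higher in C than in A and lower in D than in B (6.13% against 6.60%), a difference of −1.19 points. Coverage of the 3' end relative to the 5' end of regions over 2000 bp was 81.0% in A and 87.6% in C, and 82.1% in B and 65.6% in D, a difference of −23.1 points. This ratio depends partly on which lists set the ends of the joined regions. Each of the 4 measures had p = 0.0556 in an exact 2-sided permutation test within the levels of the first factor. This is the smallest value that its 36 arrangements allow, so the test cannot pass 0.05. Opposite directions in every list, by which the measures were picked, force this value, so it adds no evidence. The test exchanges lists between A and C and between B and D, so it removes both effects and not only their difference. In the same exact 2-sided permutation test, the measures not picked (number of peaks, number of regions and covered length) had p = 0.111. No explanation, technical or biological, was tested for the differences in the 4 measures.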

How the results depend on the processing

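Ignoring strand, joining peaks within 1000 bp, keeping only regions of at most 1000 bp (joined width), the list length alternative of median width, and all alternatives of the odds ratios of wide regions, of mean width, of the share of peaks over 1000 bp and of chromosome 19 were chosen after seeing the data. Outside the leave-one-out settings, 81 of 114 alternative values kept their direction and side of the threshold or stayed within 1.5 times the count, and 33 counts moved by more. A single count cannot reverse, but in B against A the excess of lost over gained regions (3544 and 3021) turned with every list at its 19953 best peaks (2995 and 3276). Equal list lengths draw lost and gained counts together by construction. The mean Jaccard index of replicates stayed between 0.726 and 0.768 with p = 0.00952 in the exact test in each alternative except leave-one-out, and the total over A and C against B and D between 2389 and 2996.

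With the best-scoring 50% of each list, B against A had 1997 gained regions, C against A 270 lost and 888 gained, D against C 3227 lost, D against B 680 lost and 595 gained, and A and B against C and D 23 in all. Fewer peaks enter by construction. With every list at its 19953 best peaks, C against A had 939 lost and 988 gained regions and D against C 3502 lost. Allowing a peak in 1 of the 2 other lists gave more regions by construction. B against A then had 5722 lost and 4836 gained, C against A 2046 and 4426, D against B 3246 and 2905, and D against C 4070 gained.

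Leaving out 1 list raised the counts, since presence or absence is then required in 1 list fewer. The ranges for lost and gained regions were 4460 to 5522 and 3883 to 4607 in B against A, 1242 to 1769 and 3049 to 4045 in C against A, 6241 to 7775 and 3086 to 3771 in D against C, and 2144 to 2967 and 1921 to 2650 in D against B. For A and B against C and D the total was 94 to 131. The difference in peaks ranged from −3194 to −2150, with p above 0.05 (0.0857, exact permutation, n = 3 and 4) without any 1 list of B or D. That in median width ranged from −8.25 to −6.25 bp, with p = 0.0571 (exact permutation, n = 3 and 4) without either list of B. Mean width, share over 1000 bp, similarity and odds ratios of wide regions kept their calls.

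Whether the replicate numbers pair the lists was not settled, and there are only 2 numbers. Deviations of same-numbered lists correlated at only 0.0172 to 0.0305 over regions. The split of replicates 1 against 2 changed more regions than the crossed split in every comparison. The counts were 638 and 519 in B against A, 1134 and 914 in C against A, 691 and 549 in D against C, and 894 and 694 in D against B. Replicate 2 also had more peaks than replicate 1 in A (22083 and 21979), B (21160 and 20309), C (25111 and 24183) and D (20971 and 19953). With the replicate block, a region must change in both same-numbered pairs, which is the main rule by construction, so 3544 regions were lost and 3021 gained in B against A as before. Number 1 alone gave 7031 lost and 5402 gained regions in B against A, 3068 and 5276 in C against A, 8893 and 4687 in D against C, and 3987 and 3618 in D against B. Number 2 alone gave 6673 and 5753, 2736 and 5760, 8984 and 4840, and 4050 and 3850.

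Leaving out the mitochondrial genome and unplaced sequences removed no peak. The alternatives of gene lists, U content, place in transcripts and the count test were not run, as those results were not.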

Other observations

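All tests in this part were chosen after the patterns had been seen, except the count over splits of the lists and its alternatives of list length, which were planned. Peaks of B and D were spread differently over the chromosomes than those of A and C. For 17 of 23 chromosomes (1 to 22 and X) the share of peaks in the 4 lists of B and D did not overlap that in the 4 lists of A and C. Chance gives 2.86% of chromosomes, or 0.657, if all lists are independent. Replicates lay close to each other, so with the pairs as units chance would give more. The share was lower in B and D for 6 chromosomes and higher for 11. Each had an exact permutation p of 0.0286 (adjusted 0.0387 over 23, n = 4 each) that takes the lists of a pair as independent. For A and B against C and D no chromosome separated. Chromosome 19 held 7.33% ± 0.114 of peaks in A and C and 6.42% ± 0.0861 in B and D (SD, n = 4 each). Chromosomes 22 (2.76% and 2.29%), 17 (5.30% and 4.55%) and 16 (4.26% and 3.76%) also had lower shares in B and D, and chromosomes X (3.07% and 3.78%) and 13 (1.97% and 2.34%) higher ones. Of the regions in all lists of B and D, 7.68% had no peak in A and C, but only 18 of 958 (1.88%) on chromosome 19 and 51 of 321 (15.9%) on chromosome 13. Of the regions in all lists of A and C, 11.4% had no peak in B and D, and 7 chromosomes differed from the rest in this share (Fisher's exact test over regions, adjusted p under 0.05), among them chromosomes 9 (15.7%), 22 (15.5%), 17 (15.1%) and X (5.57%). On chromosome 19 it was 12.2% (154 of 1263, adjusted p = 0.479 in the same exact test). Chromosome shares within a list sum to 100%, so the chromosomes are not independent.

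Regions that changed lay near each other. Of the 1875 regions only in A and C, 40.16% had another within 10000 bp on the same strand, against at most 16.5% in 1000 shuffles among the regions in all lists of A and C. For the 1106 regions only in B and D it was 34.0%, against at most 12.1%. The longest run held 11 successive regions over 28497 bp on the plus strand of chromosome 9, from 124519292 to 124547788, all with a peak in every list of A and C and in no list of B and D. A run of 6 such regions lay on the minus strand of chromosome 20, from 48249483 to 48273239. Of regions only in B and D, the longest run held 6, on the plus strand of chromosome 6 from 111306209 to 111337059. Loss at random places among these regions is therefore argued against. The shuffles did not hold the score fixed, and poorly scored regions changed more often. Whether poorly scored regions lie near each other, and so are lost near each other, stays open. A candidate explanation, not tested without gene positions, is that the exons of 1 transcript changed together.

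The separation of A and C from B and D may come from the condition that differs, which is IP against input by the record and AS by the names. Chance can be excluded only if the 8 lists are taken as independent: of their 35 splits 1, the real one, gave as many regions as its total of 2981, the highest other being 90, but the 3 splits that keep replicates together are too few for a share under 0.05. Unequal list lengths are argued against as the whole cause, since 2861 regions were counted with every list at its 19953 best peaks, where the highest other split gave 79. Weak peaks near the caller's threshold are argued against as the whole cause, since 564 regions were in the best-scoring 50% of each list of one side and in no list of the other, against 11 in the highest other split. A shared control library, a library batch and the true condition of each list stay open, since the sources used here give none of them.

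Wide regions were lost more often in B against A and D against C. Peaks broken into pieces in the other pair would not count as lost, since a lost region had no overlapping peak there. Poorer scores of wide peaks are argued against, since within tertiles of the score the odds ratios were 2.94 in B against A and 2.89 in D against C, and the lower of their lower bounds was 2.57. Unequal list lengths are argued against, since with every list at its best peaks the lower of the lower bounds was 1.67. In other comparisons the odds ratio within tertiles was 1.65 for loss in D against B, 1.62 for gain in D against B, 1.897 for gain in C against A and, below 1, 0.564 for loss in C against A. Sequencing depth and a biological difference by AS or by IP both stay open.

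The lower share of chromosome 19 in B and D could come from a few dense clusters of peaks, but 65.1% of the difference was kept without the 10 bins of 1 Mb per chromosome that differed most (6.74% in A and C, 6.14% in B and D), and the lists still did not overlap. It could also come from wide peaks lying unevenly over the chromosomes, but 95.3% was kept among peaks of at most 1000 bp. Both are argued against as the whole cause. Chromosomes differ in gene density and base content, and neither was tested here.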
